A study of Homo sapiens with 2 samples.

How the data were processed

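The series holds 2 samples of MDA-MB-231, an established human breast cancer cell line with a mesenchymal, triple-negative phenotype. Their titles name RNA recovered with a catenin immunoprecipitation (IP; the title writes B-catenin) and an input. Each is a single library, so nothing here has replicate error and no test across samples was possible. Per the labels' protocols, RNA of the catenin IP was extracted with phenol-alcohol and sheared to fragments of about 300 to 500 bp. The file used here belongs to the IP sample. Values of the input library on its own were not analysed here. The submitters' processing notes name the genome build hg18. The Ensembl transcript identifiers look like those of a later annotation, so the build behind the peaks is uncertain. The aligner, the peak caller, the transcript annotation and the library used as background are not given in the sources used here.

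The name of the file speaks of FPKM, but its content is a list of peaks along Ensembl transcripts and no FPKM value is in it. Each row gives a transcript, a gene symbol, an annotated region, and the start, end, length and summit of a peak in nucleotides along the transcript, counted from 1, per the file headers. The end minus the start plus 1 equalled the length in every row. The tag count is the whole number of tags in a peak, as deposited by the authors. The fold enrichment is the ratio that the authors' peak caller gave for each peak, per the file headers. A further column of the authors' has lost its name to a spreadsheet and is called the score here. Its place in the table and its minimum of 30 are those of a scaled negative logarithm of a p-value in common peak callers, but the file does not say so. The score was used only to filter peaks. It stopped at 3100 in 24 peaks and reached 3228. Fold and score are the peaks' own values from the authors and serve only to describe, rank or filter peaks within this list. KEGG pathways are those the authors joined to the transcripts.

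A gene with several annotated transcripts was listed once per transcript with nearly the same tags, so each symbol was represented by the transcript with the most tags over its peaks. A gene's tags are the sum over the peaks of that transcript, and its fold is that of its highest peak. Tags per kb are tags divided by the length of the peaks. The total depth of the library is unknown from these sources, and the sum of tags over peaks is not a depth. Exact Poisson intervals for tag counts and exact Clopper-Pearson intervals for shares are at 95% and cover counting error only; tags without molecular identifiers are not independent molecules.

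The design fixed before the data were examined had assumed expression values for both libraries. It asked for ratios of IP to input on a log2 scale, which could not be computed. The authors' fold took the place of that ratio. For this case the design named genes by their level: 20 lncRNA genes, the 10 highest protein-coding genes, CTNNB1 and the 2 highest members of each gene list. Fold took the place of the level, and since 19 lncRNA genes had a peak, all could be described. The 10 genes with the most tags were added after the values were seen. The gene lists (21) and symbol families (4) were fixed beforehand. List names absent from the file were also looked up under unambiguous older symbols. To say where the median fold of a list stood, it was set against 10000 random lists of the same size, drawn from the other genes with a peak and matched on tags per gene in 20 bins. This percentile describes the 1 library and is not a p-value. Apart from 1 lncRNA setting, it took no account of whether folds lay on the multiples of 0.5788 described below. Since the file lists only RNAs that passed the authors' threshold, absence from it means only that no peak was listed.

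Of the 1658 symbols, 1592 were found in the RefSeq table for GRCh38.p14, 46 under an older symbol and 20 not at all. That table served for names and gene types only. Its coordinates were not used because the submitters' notes name another build, so positions are given along transcripts. One symbol had been turned into a date by a spreadsheet and was not named. Values of some single genes are not reported here.

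The procedures were tested on simulated data. A step planted in simulated folds was recovered as 0.6432, with 60.5% of simulated peaks found on its multiples where 59.8% had been planted. With 50 lists of 20 genes whose fold was doubled, 50 came out above the central 95% of random lists, and 2 of 50 unchanged lists fell outside it. Folds had first been shuffled over genes, so the matching on tags was not tested. A doubling is also larger than the difference between lncRNA and other genes described below. Alternatives were a 4-fold minimum, each transcript on its own, curated lncRNA names only, score minimums of 50 and 100, merging of symbols with identical peaks, another choice of transcript, unmatched random lists and, for the lncRNA median, only genes with every peak on the multiples of the fold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.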

Results

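RNA recovered with a catenin immunoprecipitation from MDA-MB-231 breast cancer cells was sequenced together with an input, with the stated purpose of screening for long noncoding RNAs (lncRNAs) that bind catenin. The list of enriched regions held 6195 peaks on 4439 transcripts of 1658 gene symbols. With 1 transcript per gene, 2440 peaks remained, and 1136 genes had a single peak. Peaks carried 11 to 3078 tags, with a median of 27 over the 2440 peaks, and their lengths ran from 294 to 16902 nt. The fold enrichment of the authors ranged from 2.55 to 89.72. The median over genes was 7.56, with quartiles of 5.79 and 11. In 70.1% of the 2440 peaks the fold was a whole multiple of 0.5788, to within 0.0051, so that among these peaks it took only stepwise values. These values come from 1 IP library, so differences between genes have no replicate check.

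On the lncRNA question, 19 gene symbols annotated as lncRNA had 26 peaks, which made up 1.15% of the symbols and 0.704% of the 133739 tags over the 2440 peaks. The highest fold belonged to LINC00504, an intergenic lncRNA, at 23.15 with 43 tags (Poisson interval 31.1 to 57.9). UGDH-AS1, annotated antisense to UGDH, followed at 18.52 with 91 tags (73.3 to 112). Both folds were whole multiples of 0.5788. If such folds have a denominator held at a floor, as described below, they rank summit height and not enrichment over a measured input. NEAT1, the architectural RNA of nuclear paraspeckles, had 5 peaks with 168 tags and a highest fold of 15.04. NORAD, a cytoplasmic RNA that binds PUMILIO proteins, had the most tags of the group, 190 (164 to 219), at a fold of 11.26.

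Along the NEAT1 transcript ENST00000501122, 4 of the 5 peaks lay between nt 588 and 5797, and the remaining peak lay at nt 17861 to 18646 with 24 tags. The peak with the highest fold covered nt 2818 to 3643. NORAD (ENST00000565493) carried a single peak from nt 548 to 5123. In KCNQ1OT1 (ENST00000597346), the antisense RNA of the imprinted KCNQ1 domain, both peaks lay at nt 62834 to 64890, with 48 tags and a highest fold of 8.68. TUG1, an abundant RNA found in nucleus and cytoplasm, had 3 peaks at nt 4 to 4417 of ENST00000519077, also with 48 tags, and a highest fold of 7.52. The LINC00504 peak covered nt 485 to 1037 of ENST00000505089, and the UGDH-AS1 peak nt 825 to 2374 of ENST00000504032.

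The other 13 lncRNA symbols had folds from 5.79 to 12.73. Of the remaining antisense RNAs, AFAP1-AS1 stood at a fold of 9.26 with 26 tags and FRMD6-AS1 at 8.10 with 15. GABPB1-AS1 and WAC-AS1 both stood at 5.79, with 16 and 24 tags. The sense genes of 3 of the 5 antisense RNAs also had peaks: AFAP1 had a fold of 19.87, UGDH 14.28 and WAC 12.34. Whether the counting used strand is not given in the sources used here, so for these pairs sense and antisense tags may not be separable. The reference table typed 9 of the 19 symbols as lncRNA, TUG1 as protein-coding and EBLN3P as a transcribed pseudogene. EBLN3P had a fold of 5.79 with 20 tags. The other 8 symbols were clone-based names without an entry in the reference table, led by RP11-346D14.1 at 12.73 with 83 tags. Among them, CH507-513H4.1 and CH507-528H12.1 had peaks at the same positions with 30 and 31 tags, and whether the same reads were counted for both is not known.

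**Figure D1:**
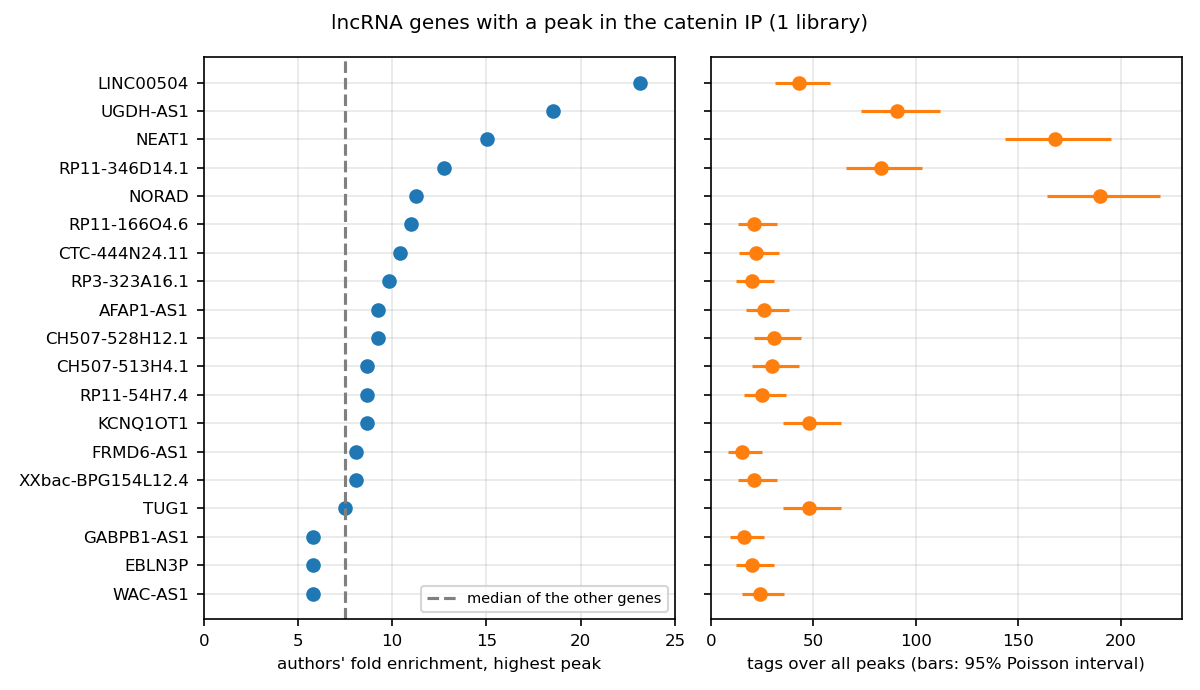
Fold enrichment of the highest peak (left, authors' values) and tags over all peaks (right, with 95% Poisson intervals) for the 19 lncRNA genes with a peak; the dashed line is the median fold of the other genes, 7.52. LINC00504 and UGDH-AS1 lead by fold, and NORAD and NEAT1 by tags. In 17 of the 19 genes every peak has a fold on the multiples of 0.5788.

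The median fold of the 19 lncRNA genes was 9.26, against 7.52 for the 1639 other genes, while their median tags were lower, 26 against 41. Against random lists matched on tags, whose median fold was 7.52, the lncRNA median stood at percentile 98.2. Without matching it stood at percentile 89.5, and with the 11 symbols found in the reference table alone, TUG1 and EBLN3P included, at 81.8. In 17 of the 19 lncRNA genes every peak had a fold on the multiples of 0.5788, against 993 of the 1639 other genes. Among these genes alone the medians were 8.68 and 8.10, and the lncRNA median stood at percentile 85.0 of matched random lists. A higher fold of lncRNAs as a class therefore did not hold in every setting.

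Among the other genes, the largest fold was that of MAP1B, a microtubule-associated protein, at 89.72 with 1313 tags in a single peak at nt 249 to 9728 of ENST00000296755. TLN1, the integrin-linking protein talin, followed at 64.25, reached in a peak at nt 320 to 1697 of ENST00000314888 that held 214 of its 286 tags. ANKRD11, a chromatin regulator, had a fold of 57.88 with 958 tags at nt 278 to 5698 of ENST00000301030. PLEC, the cytolinker plectin, had 8 peaks, the largest number of any gene, and a highest fold of 49.2. The other 6 of the 10 highest were all NBPF genes (NBPF9, NBPF14, NBPF26, NBPF10, NBPF20 and NBPF19), with folds from 46.88 to 52.67. NBPF genes are near-identical copies, and 8 of the 14 protein-coding NBPF symbols of the reference table had a peak. How reads shared between copies were counted is not given, so their individual values are uncertain.

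CTNNB1, which encodes beta-catenin, carried more tags than any other gene. Its peak held 3078 tags (Poisson interval 2970 to 3189), 2.30% of the tags over the 2440 peaks (exact binomial interval 2.22 to 2.38%) and 2.03 times those of NBPF20, the next gene. It spanned nt 195 to 3026 of ENST00000349496, was annotated to reach both untranslated regions, and had its summit at nt 1970. The density was 1087 tags per kb of peak. NCL, which encodes nucleolin, ranked second at 363 tags per kb, and the median over genes was 29.8. By fold, CTNNB1 stood at 8.99 and ranked 630 of 1658. Its fold was not on the multiples of 0.5788, so this rank sets it beside many folds that may have a denominator at a floor. The 543 genes with fewer than 50% of their peaks on the multiples, CTNNB1 among them, had a median fold of 6.43. The 3 listed transcripts of CTNNB1 had 3077 or 3078 tags each, all at a fold of 8.99.

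After CTNNB1 and NBPF20, the most tags lay on MYH9, the heavy chain of nonmuscle myosin (1387 tags, fold 29.19), MAP1B, and AHNAK, a giant scaffold protein (1295 tags, fold 27.78). SPTBN1, the spectrin beta chain, had 1052 tags at a fold of 27.32, and NCL had 939 tags at 11.94. Of the 10 genes highest by tags, 5 were among the 10 highest by fold.

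**Figure D2:**
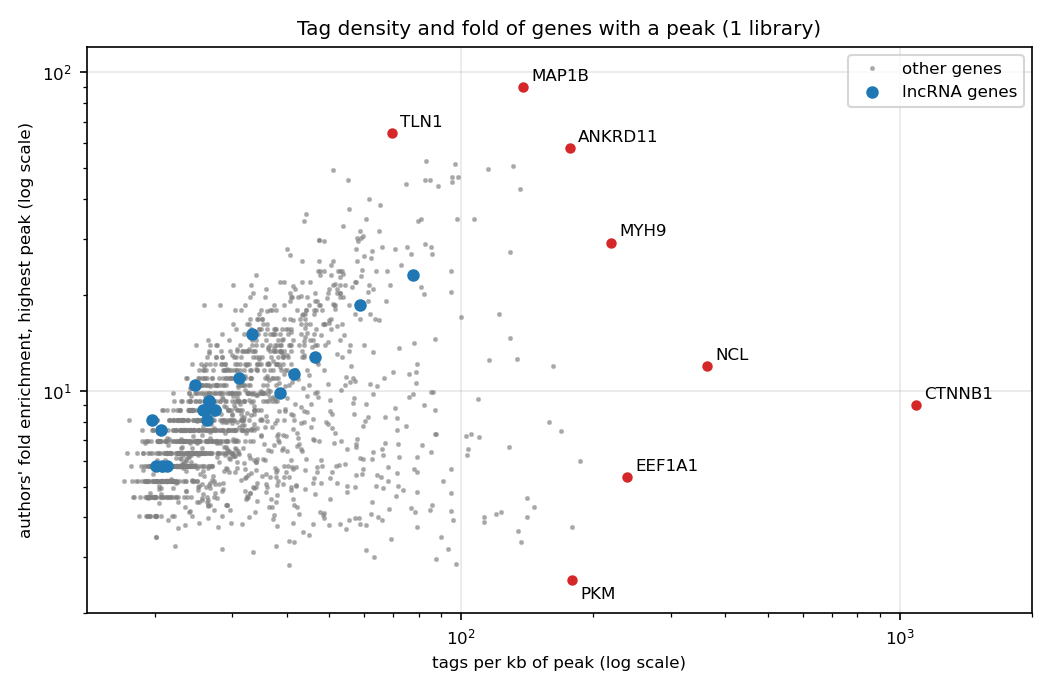
Tags per kb of peak (horizontal, log scale) against the authors' fold enrichment of the highest peak (vertical, log scale), with a point per gene, lncRNA genes in blue and named genes in red. CTNNB1 lies far right of all other genes at 1087 tags per kb, with a fold of 8.99, and MAP1B lies highest at 89.72.

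In the Wnt pathway, in which beta-catenin is the transcriptional effector, 8 of 39 components had a peak, led by FBXW11, a substrate adaptor of the ubiquitin ligase that acts on beta-catenin (fold 9.84, 20 tags), and CTNNB1. The others were TLE3, APC, GSK3B, CSNK1A1, BCL9L and TCF7L2, with folds from 5.79 to 8.68 and 12 to 95 tags. Only 4 of the 8 had a peak with a score of at least 50. Of 27 Wnt target genes 2 had a peak, CCND1 (cyclin D1; fold 8.79, 125 tags) and SOX9 (fold 5.79, 16 tags). The median fold of the pathway components, 6.37, stood at percentile 43.9 of matched random lists.

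Adherens junction genes, whose proteins bind beta-catenin or act beside it, had a peak in 7 of 19 cases. TJP1, the tight junction scaffold ZO-1, stood at 29.52 with 282 tags and the phosphatase gene PTPN14 at 18.52 with 112. The scaffold gene AFDN stood at 12.73, CTNND1 (p120 catenin) at 9.26 and VCL (vinculin) at 8.85. LIMA1 stood at 5.13 and CTNNA1, the alpha-catenin that binds beta-catenin directly, at 4.29 with 179 tags. Their median of 9.26 was at percentile 17.2.

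The share of all annotated genes with a peak was not computed, so the shares of the lists can only be set against each other. It was highest among genes of very large proteins, 19 of 24. These were led by PLEC and by DYNC1H1, the dynein heavy chain (fold 28.36, 789 tags). Their median fold of 14.47 stood at percentile 89.4. Splicing factor and nuclear speckle genes had a peak in 9 of 24 cases, led by the speckle proteins SRRM2 (38.2, 416 tags) and SON (34.73, 281 tags), with HNRNPA1 lowest at 3.73. Their median of 10.39 was at percentile 25.8. Proliferation genes had a peak in 6 of 24 cases, led by MKI67 (28.36, 833 tags) and TOP2A (26.78, 388 tags), and their median of 22.58 was at percentile 95.8. Of 23 actin and tubulin cytoskeleton genes 4 had a peak, led by TLN1 and MYH9, with a median of 23.09 at percentile 55.4. None of the actin, tubulin or tropomyosin genes of that list was listed.

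Mesenchymal and basal breast cancer genes had a peak in 4 of 18 cases, led by FN1 (fibronectin; 18.0, 413 tags) and EGFR (11.39, 318 tags), with a median of 8.88 at percentile 10.9. Zinc finger genes of the ZNF series had one in 40 of 517 cases, led by ZNF367 (23.15) and ZNF460 (15.05), with a median of 7.24 at percentile 79.2. In the glycolysis list 3 of 19 genes had a peak. HK2 stood at 11.58, HK1 at 7.77 and PKM at 2.55, the lowest fold of the whole list, and their median was at percentile 13.3. Of 20 translation factors EEF1A1 (5.37, 552 tags) and EIF4B (5.36, 205 tags) had a peak. Of 19 heat shock and unfolded protein genes HSPH1 (5.11) and HSPA5 (4.02, 356 tags) did.

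Several groups of abundant or short RNAs were nearly or wholly absent. Of 87 cytosolic ribosomal protein genes 3 had a peak, led by RPS3 (9.84, 21 tags) and RPL27A (5.45, 12 tags), with a median at percentile 9.89. No peak was given for the 26 listed nuclear-encoded oxidative phosphorylation genes, the 15 mitochondrially encoded genes or the 79 histone genes matched by symbol. The 25 small structured noncoding RNAs, the 20 snoRNA host genes and the 18 immediate early genes had none either. For the small structured RNAs this may have been fixed in advance. The region labels held no class for them, and the shortest peak had 294 nt. Among the fixed lncRNA lists, 3 of 15 in the nuclear-retained list (NEAT1, KCNQ1OT1 and TUG1, the last also found in the cytoplasm; median at percentile 46.9), 1 of 12 cytoplasmic lncRNAs (NORAD) and 1 of 38 cancer-associated lncRNAs (AFAP1-AS1) had a peak. MALAT1, an abundant nuclear lncRNA, had none. Of antisense and intergenic lncRNA names, 6 of 4378 had a peak, led by LINC00504 and UGDH-AS1, with a median at percentile 92.0. Markers of other cell types were absent as well, with 0 of 15 luminal epithelial and 0 of 12 immune and blood genes. Only 4 of 18 mesenchymal and basal genes had a peak, so such absences do not tell cell types apart. Of the 25 lists and families, 12 held at least 3 genes with a peak, and the median fold of 0 of these lay outside the central 95% of matched random lists. Apart from the very large proteins (19 genes) and the zinc finger genes (40), these lists held at most 9 genes. The simulated lists held 20 genes, so whether a real difference would show in such short lists was not tested.

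**Figure D3:**
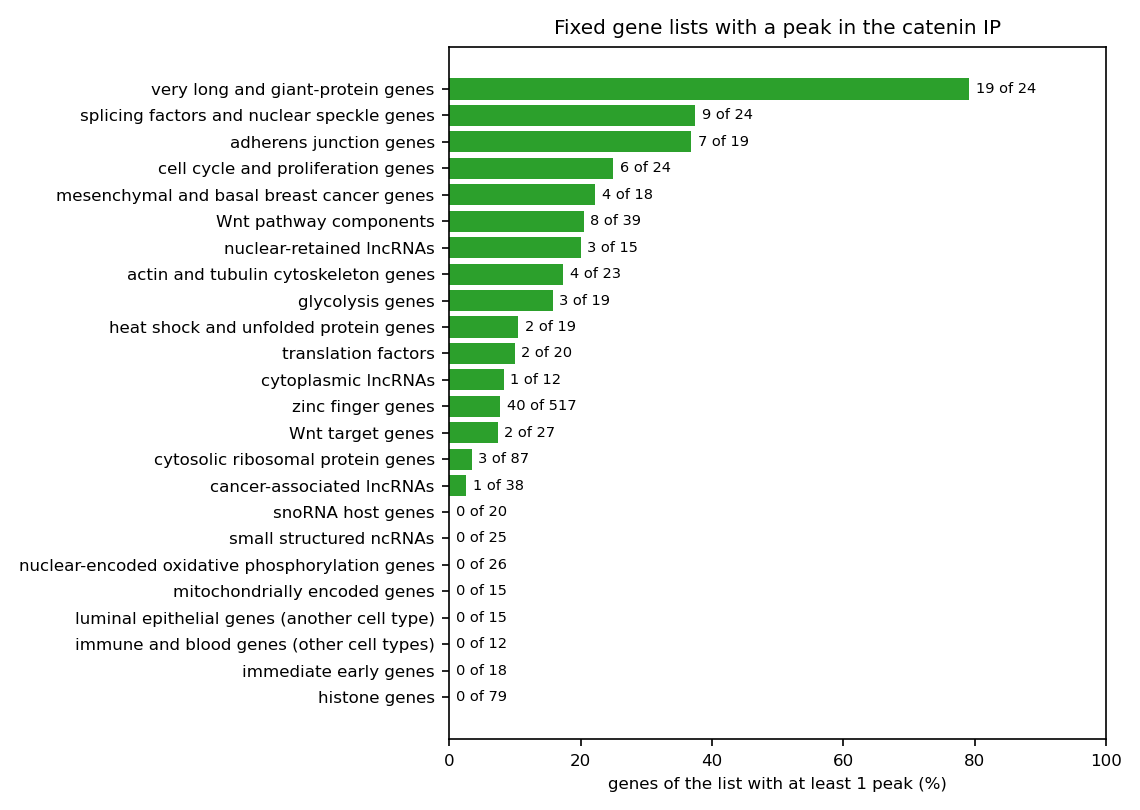
Share of the genes of each fixed list with at least 1 peak (bars, in percent of the list; counts beside the bars). The list of very large proteins leads with 19 of 24, and 8 lists have none; the family of antisense and intergenic names, 6 of 4378, is left out.

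By annotated region, 39.7% of the 2440 peaks (969; exact binomial interval 37.8 to 41.7%) lay in coding sequence alone and 28.2% (687) in the 3' untranslated region alone. A further 19.7% were annotated to the 3' untranslated and coding regions together, 8.65% to the 5' untranslated and coding regions, 2.30% to both untranslated regions and 0.41% to the 5' untranslated region alone. The median fold ranged from 6.66 to 9.09 between these classes. The labels contradicted the positions in many transcripts. In 92 of 137 comparisons, a peak labelled 3' untranslated and coding lay upstream of every coding-only peak of the same transcript, where a 3' end cannot lie. The corresponding label for the 5' end lay upstream in 40 of 43. Peaks labelled 3' untranslated alone lay upstream in 54 of 100, so the share of 28.2% for that label is uncertain too. The distinction between 5' and 3' regions was therefore not used further.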

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

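The score minimums, the merging of symbols, the choice of transcript by fold, the unmatched lists and the restriction to multiples of the fold were chosen after seeing the data. No paired analysis was possible because each group has 1 library. The settings for pseudocounts, low-value filters, centring, scaling and transcript length, and the agreement of the libraries, that had been set beforehand were not run, since they need expression values or lengths that are not in the peak list. Each transcript counted on its own gave 4439 enriched transcripts, 371 of them on genes of the fixed lists (119 genes in the main count), with 34 for the Wnt components, 56 for adherens junction genes, 22 for splicing genes and 69 for very large proteins. It also raised the coding-only share to 47.2%; more units are counted by construction. A score of at least 100 left 670 genes, 6 lncRNA genes with a median fold of 13.88, a coding-only share of 35.7%, 58 list genes and 1 Wnt component, CTNNB1; a score of at least 50 left 4 Wnt components. Curated names alone left 11 genes, of which the reference table types 9 as lncRNA. The percentile of the lncRNA median, 98.2 in the main setting, was 89.5 without matching, 81.8 with curated names, 89.7 at a score of at least 50 and 85.0 with only the genes that have every peak on the multiples of 0.5788, where the lncRNA median fold was 8.68. The cause was not tested. Under a 4-fold minimum the lncRNA count stayed at 19 and the gene count was 1611. Merging symbols that share an identical peak of at least 20 tags gave 1652 symbols, and symbols sharing only smaller peaks were not merged. Of 55 further values (single lists and CTNNB1) under alternatives, 37 stayed within 1.5 times and 18 moved further. CTNNB1 ranked 1 by tags under both score minimums. Many genes rest on few tags: the median gene had 41, the median peak 27 and the weakest peak 11.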

Other observations

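The KEGG annotation joined by the authors gives groups of genes other than the fixed lists, with some genes in both. It placed 27 genes with a peak in the adherens junction pathway, among them the histone acetyltransferase gene EP300 (fold 35.89, 256 tags), LMO7 (15.05), IQGAP1 (13.63, 436 tags), the SRC-family kinase gene YES1 (13.31) and SMAD3 (12.16), and 24 in the Wnt pathway. The medians of both, 8.99 and 7.45, stood at percentiles 62.4 and 16.4 of random lists matched on tags. In the spliceosome pathway 28 genes had a peak, led by RBM25 (34.73), SNRNP200 (18.66) and ACIN1 (17.36), with a median of 7.58 at percentile 0.56. Of 88 pathways with at least 10 genes, 3 lay below and 0 above the central 95% of random lists, where chance gives 4.4 outside, so no pathway stood apart by fold beyond what the number of pathways gives. These pathways were examined after the fixed lists.

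The tests on CTNNB1 and on the multiples of the fold below were chosen after the values were seen; those on giant-protein genes were set before their result was seen. In 70.1% of the 2440 peaks the fold was a whole multiple of 0.5788 to within 0.0051. Over all 6195 peaks the share was 71.6%, against a mean of 1.68% and at most 9.54% for 100 other steps, all somewhat smaller. This is consistent with a denominator held at a floor of 1.73 tags wherever the background was lower. The fold of such a peak is then proportional to its summit height in tags, and ranks by fold among them are ranks by height, not by enrichment over a measured input level. Of the 20 genes with the highest fold, 18 had their highest peak, which sets the rank, on these multiples; AKAP12 and NBPF15 did not. The 1115 genes with at least 50% of their peaks on them had a median fold of 8.10, and the other 543 genes one of 6.43.

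Where the fold is off those multiples, the background can be estimated. In the 1710 peaks on the multiples, summit height was 0.503 times the tags per kb (5th to 95th percentile 0.367 to 0.727), and applied to CTNNB1 this gives a background of 60.8 tags, 35.2 times the floor and the highest of all peaks. PKM came next at 35.4, and EEF1A1, among the most abundant mRNAs of most cells, had 22.4. With the ratio of peaks with at least 60 tags per kb, 0.641, CTNNB1 had 77.5. Its tag density was the highest of all genes, so either value is an extrapolation. A background drawn from the IP library itself is argued against, because 11 of the 20 tag-richest peaks of other genes sit on the floor; carry-over of IP reads at a constant share is argued against by 268 genes with a fold of more than 1.5 times that of CTNNB1. Uneven coverage stays open for the order against PKM: at the 5th percentile of the ratio CTNNB1 has 44.3 tags, above EEF1A1 at the 95th (32.4) but not PKM (51.1). What stays open, as a hypothesis that no test here decides, is that CTNNB1 RNA may itself have been very abundant in the background library; no biological explanation was tested.

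Giant-protein genes had peaks in 19 of 24 cases, while the listed oxidative phosphorylation genes and the histone genes matched by symbol had none. Outside these lists, the oxidative phosphorylation gene NDUFA9 (fold 19.1, 34 tags) and the histone variant gene H2AFV (16.27, 40 tags) had a peak. The tag density of the giant-protein genes, a median of 29.99 tags per kb of peak, stood at percentile 53.2 of random lists (median 29.7). Only genes with a peak enter that comparison, so it does not decide whether longer RNAs have peaks because they collect more tags at a like density, and this stays open. A higher background on short abundant mRNAs stays open too: the median farthest peak end was nt 2950 over the 1115 genes with at least 50% of their peaks at the floor and nt 2083 over the others, a ratio of 1.42, between the bounds set for either reading. Transcript lengths were not used here, and no biological explanation was tested.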
